A study of Mus musculus with 12 samples.

How the data were processed

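The series holds 12 microarrays of B16-F10 cells, an established mouse melanoma line. Per the labels, the cells were transfected with the empty vector pMES, with pMES carrying chicken FoxD3, or with pMES carrying FoxD3-VP16, in which the C-terminal repression domain of FoxD3 gave way to the activation domain of the viral protein VP16. Each vector also makes EGFP from the same transcript. EGFP-positive cells were sorted 24 h after transfection, RNA was taken with Trizol, amplified to biotin-labelled antisense RNA and hybridized to 1-colour arrays, per the labels' protocols. The 3 groups have 4 arrays each, and groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

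The values deposited by the authors are a linear intensity for each of 45101 probe sets on each array. MAS5 is the tool named per the submitters' processing notes, and its version is not given in the sources used here; a label names dChip for the authors' own analysis. In the deposited values the mean without the lowest and highest 2% of probe sets lies between 500.003 and 500.004 on all 12 arrays, so the arrays share one scale factor rule. Detection calls were not used here. Medians of log2(intensity + 16) nevertheless spanned 0.79 between arrays.

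From these values log2(intensity + 16) was computed, and quantile normalization was applied because the medians spanned more than the limit of 0.5 that had been set for it. Changes are therefore on the log2(intensity + 16) scale, which understates the change of dim genes. The 64 control probe sets were left out. Gene symbols came from the platform's annotation table: 34945 probe sets had 1 symbol, 932 had several and 9160 were not listed, and the last 2 kinds entered no gene test. Of the probe sets of a gene, the one with the highest mean over the 12 arrays was taken, giving 18193 genes. The lowest 40% by mean (below a log2 value of 5.98) were left out, which left 10916 genes tested.

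Each of the 3 pairs of groups was compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) over all 12 arrays, which share 1 estimate of the spread, without a block. There were 9 residual degrees of freedom and 3.98 prior ones. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 are called changed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

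A total of 29 gene lists with 726 distinct genes was fixed; 676 of the genes are on the array and 471 were tested. Each list with at least 5 tested members was tested with camera at the preset inter-gene correlation of 0.01, adjusted over the 27 such lists per comparison. The result of 1 of these lists is not reported here. Beside it stand camera with an estimated correlation, fry, and the number of members past the threshold, both over all genes and adjusted over the list alone. The lists cover pigment, melanocyte, neural crest, glial, neuronal and pluripotency genes, genes reported to respond to FOXD3, the cell cycle, stress, signalling, housekeeping and markers of other cell types.

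Named genes followed a fixed rule: for each comparison the 10 largest rises and 10 largest falls among called genes whose 4 arrays of one group all lay above or below the 4 of the other; up to 5 genes per pattern of directions in the overlap; up to 4 called members of each list that passed and of 7 lists in any case; and 18 genes given whether or not they passed. The groups, the tests, the lists, this rule and the alternatives were set before the data were examined, except where a later choice is stated.

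The groups share the replicate numbers 1 to 4, so it was checked whether the numbers pair the samples. Deviations from the group means correlated across genes at 0.37 to 0.67 in all 12 pairs of arrays with the same number, at 0.37 to 0.54 in the 6 pairs joining numbers 3 and 4, and at -0.51 to 0.12 in the 30 other pairs of arrays of different groups. The replicate numbers were thus taken to pair the samples, but the main fit, set beforehand without a block, leaves the pairing aside. Its error holds the spread between numbers, so a gene it does not call is not shown to be unchanged. The fit with the number as a block has 6 residual and 7.30 prior degrees of freedom. It stands beside a result wherever it changes the call of a list, or of a gene in a comparison for which the rule names it. It also stands there where it moves a count over all tested genes by over 1.5 times. Counts of list members are given without it. The source of the pairing is this correlation; the labels do not say what the numbers share.

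The calculation was tested on simulated data for FoxD3 against empty vector, with 200 of 10916 genes changed, in 10 runs. Without the block it recovered 1.49%, 34.8% and 81.5% of log2 changes of 0.5, 1 and 2, with 0.1 false calls among 78.2 on average. With the block it recovered 34.2%, 74.6% and 95.9%, with 6.1 false calls among 142.3. For lists, a shift of 0.5 was recovered in 20 of 20 runs, and 1 of 520 unchanged lists was called. The simulated noise was independent between genes, so these runs do not show how often camera calls unchanged lists of correlated genes.

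The alternatives were: the values as deposited; pseudocounts of 1 and 64; no filter, or the lowest 60% left out; the block; the mean of all probe sets of a gene; probe sets ending in _x_at left out; array quality weights; a log2 change of at least 1; only the 8 arrays of the groups compared; an estimated inter-gene correlation; and each of the 12 arrays left out in turn. After the data had been seen, the fit without the 3 arrays numbered 1, with and without the block, and a block of 3 levels joining numbers 3 and 4 were added.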

Results

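RNA levels were measured in B16-F10 cells, a pigmented mouse melanoma line, sorted for EGFP 24 h after transfection with the empty vector, FoxD3 or FoxD3-VP16, with 4 arrays per group. FoxD3 is a forkhead transcription factor of the early neural crest, the embryonic tissue from which melanocytes and glia arise. The design asks which genes respond to FoxD3 and whether exchanging its repression domain for an activation domain changes that response. The transgenes are chicken sequences, and the probe set of mouse Foxd3 had a mean log2 value of 4.71, with 9.69% of the 18193 genes below it; it was not tested (log2 changes 0.11 with FoxD3 and -0.09 with FoxD3-VP16) and does not check the labels.

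The arrays differed more by replicate number than by vector. The number accounted for 50.1% of the variance over the tested genes and the vector for 30.8%. The 3 arrays numbered 1 stood apart from the others: their hybridization controls had a mean log2 value of 14.9 ± 0.15 (SD, n = 3) against 12.1 ± 0.07 for those numbered 3, their 18S ribosomal probe sets 12.9 ± 0.13 against 9.86 ± 0.10, and their Gapdh 3' minus 5' log2 difference, a sign of RNA quality, 0.66 ± 0.10 against -0.17 ± 0.04. The arrays numbered 2 had hybridization controls between these, at 13.2 ± 0.10. Their 18S probe sets were at 9.92 ± 0.22 and their Gapdh difference was -0.01 ± 0.05. With the pairing left aside, none of the 5 array measures differed detectably between vectors (exact two-sided permutation tests of 4 against 4 arrays, p = 0.371 to 0.971, adjusted p = 0.971 for each of 15 tests; the lowest p this design allows is 0.0286). Within pairs of the same number, the hybridization controls were lower with FoxD3 than with the empty vector in 4 of 4 (mean log2 difference -0.14 ± 0.08, SD). The array medians were higher with FoxD3-VP16 than with FoxD3 in 4 of 4 (0.08 ± 0.09). The exact two-sided sign permutation test of these pairs, added after the data had been seen, gave p = 0.125 for both, the lowest that 4 pairs allow, and 0.375 to 1 for the 13 other comparisons (adjusted p = 0.75 to 1 over the 15). Each vector had 1 array of every number.

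**Figure D1:**
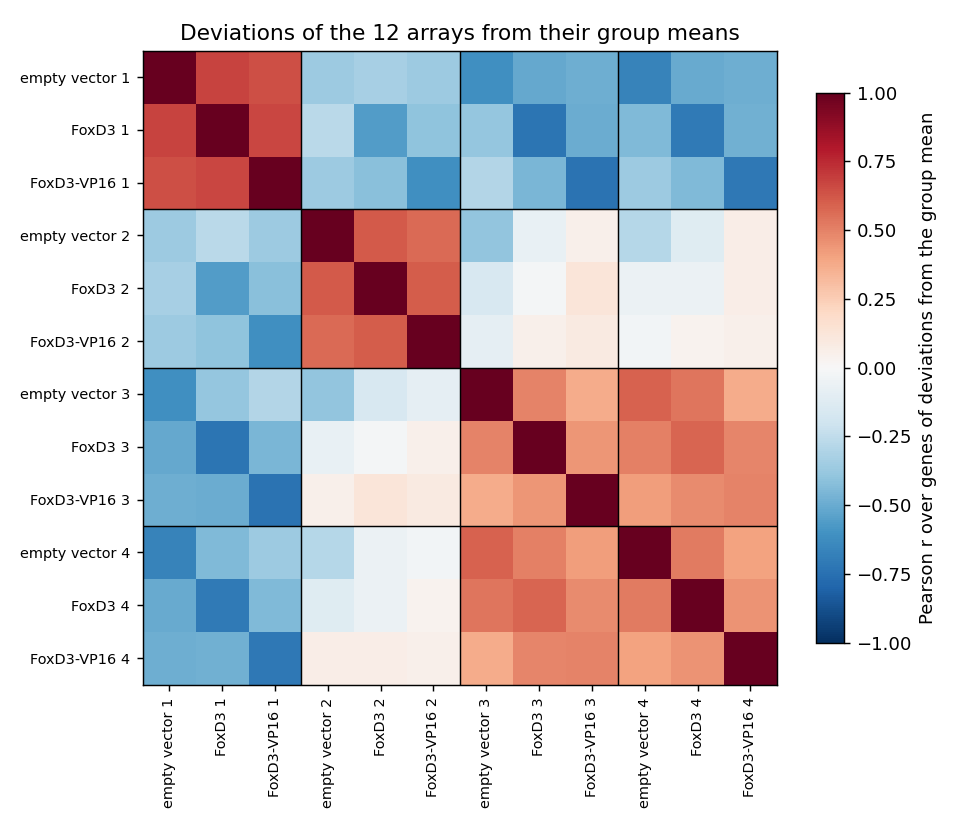
Pearson correlation (colour), across tested genes, between the deviations of every pair of the 12 arrays from their group means. Between arrays of different groups, those with the same replicate number correlated at 0.37 to 0.67 and numbers 3 and 4 with each other at 0.37 to 0.54, the remaining pairs lying between -0.51 and 0.12; pairs within a group are lowered by the subtraction of their shared mean.

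FoxD3 against empty vector. With FoxD3, the melanocyte regulators Mitf and Pax3 fell while Sox10, the neural crest and glial growth factor receptor Erbb3 and the neurotrophin receptor Ngfr rose. Mitf, the transcription factor that drives pigment cell genes, went from a log2 level of 13.4 ± 0.26 (SD, n = 4) to 12.3 ± 0.39, a 2.13-fold fall (log2 change -1.09, SE 0.18, adjusted p = 0.00483). Pax3, which acts upstream of Mitf, was 2.07-fold lower (-1.05, SE 0.17, adjusted p = 0.00421). Sox10, which specifies neural crest, melanocytes and glia, was 1.66-fold higher (0.73, SE 0.11, adjusted p = 0.00287), Erbb3 1.95-fold higher (0.97, SE 0.16, adjusted p = 0.00367) and Ngfr went from 5.27 ± 0.86 to 8.27 ± 0.41 (SE of the difference 0.47, adjusted p = 0.00287). All 5 changed the same way in 4 of 4 pairs of arrays with the same number. With the mean of all its probe sets Erbb3 had a change of 0.50 and did not pass (adjusted p = 0.170; 2.13e-06 to 0.170 over 24 alternatives).

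By the probe sets taken, the largest rise was in Col2a1, the chain of cartilage collagen, to a log2 level of 9.52 ± 0.99 (SD, n = 4; log2 change 4.52, SE 0.54, adjusted p = 0.000627). It was followed by Scube3, a secreted protein with EGF-like repeats (4.00), the crosslinking enzyme Tgm2 (3.88), the arginine deiminase Padi3 (3.75), the stress-induced Gadd45b (3.52), the fatty acid binding protein Fabp3 (3.44), placental growth factor Pgf (3.24), the matrix protein Sned1 (3.17), the myelin enzyme Cnp (3.13) and the amino acid transporter Slc38a3 (3.11). Another probe set of Tgm2, nearly as bright as the one taken, had a change of 4.98, above that of Col2a1. With the empty vector Col2a1, Scube3, Tgm2, Padi3, Sned1, Slc38a3, Ngfr, Mfng, Pdgfb, Col1a1 and Prph lay below the brightness limit of 5.98, so the size of their rise depends on the pseudocount (for Col2a1 from 3.27 to 5.69, for Ngfr from 2.00 to 3.88 over the alternatives). The largest falls were smaller. They were in the anion transporter Slc26a7 (-1.86), the zinc finger factor Klf6 (-1.72), the deubiquitinase Otud1 (-1.58), the aryl hydrocarbon receptor Ahr (-1.47), Thsd7a (-1.46), the planar polarity gene Prickle1 (-1.46), Arid5b (-1.40), the BMP and TGF-beta pseudoreceptor Bambi (-1.38), Fign (-1.36) and Zfp608 (-1.34).

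Of the 24 tested genes of melanosomes and pigment synthesis, 0 rose and 2 fell by limma over all genes (adjusted over the list alone, 0 rose and 6 fell): Rab38 (-0.66, adjusted p = 0.00149) and Rab32 (to 9.01 ± 0.34, SD, n = 4; adjusted p = 0.0393 by limma), small GTPases that carry pigment enzymes to melanosomes. Rab38 did not pass with the values as deposited (adjusted p = 0.0973; 6.29e-07 to 0.0973 over 24 alternatives). The list as a whole was lower (camera, adjusted p = 0.00955; adjusted p = 0.236 with an estimated correlation). Tyr, the first enzyme of melanin synthesis, had a log2 change of -0.78 (adjusted p = 0.0998) and Tyrp1 of -0.28 (adjusted p = 0.0994); with the replicate number as a block both fell (adjusted p = 0.000406 and 0.00203). The copper transporter Atp7a of this list (-0.60) also fell with the block (adjusted p = 0.000535) and not without it (0.140). Dct, Pmel and Mlana, abundant pigment genes, had changes of -0.07, -0.12 and -0.13 and passed in neither fit. Dct and Mlana had mean log2 levels of 15.4 and 14.9 over all arrays. That is near the top of the range, where a change may be understated in any comparison. They are thus not shown to be unchanged.

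Among 19 melanocyte lineage regulators, 1 rose and 5 fell (the same counts adjusted over the list alone). Sox10 was the riser; beside Mitf and Pax3, the survival gene Bcl2 (-1.09, adjusted p = 0.0182), the crest factor Tfap2a (-0.95, adjusted p = 0.00213) and Snai2 (-0.76, adjusted p = 0.0429) fell. The list was lower (camera, adjusted p = 0.0174; adjusted p = 0.168 with an estimated correlation). Among 16 neural crest specifiers, 2 rose (Ngfr and Sox10) and 4 fell, including Alx1, a homeobox gene of cranial crest (-1.17, adjusted p = 0.00099); adjusted over the list alone, 4 rose and 7 fell. The crest and glial factor Sox9 (-0.66, SE 0.40, adjusted p = 0.479) and the endothelin receptor Ednrb (-0.43, SE 0.51, adjusted p = 0.784) did not pass; Sox9 passed without the 3 arrays numbered 1 (-1.15, adjusted p = 0.0447) and with array quality weights (-0.93, adjusted p = 0.00183; 0.00183 to 0.758 over 23 alternatives). The receptor Kit (0.82, higher in 4 of 4 pairs) and the crest factor Twist1 (-0.33) were too dim on average to be tested. Camera placed this list lower (adjusted p = 0.0412; adjusted p = 0.168 with an estimated correlation). With the block it did not pass (adjusted p = 0.100), nor with the values as deposited (0.0909; 0.0351 to 0.222 over 19 alternatives). Tfap2a has another probe set of nearly the same brightness, with a change of -0.65, which is used when the values are taken as deposited and then does not pass (adjusted p = 0.269; 3.5e-07 to 0.589 over 24 alternatives).

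Of 13 glial and Schwann cell genes, 4 rose and 1 fell (the same counts adjusted over the list alone). Cnp rose from 9.08 ± 0.51 (SD, n = 4) to 12.2 ± 0.25 (adjusted p = 2.08e-05), and Ngfr, Erbb3 and the tetraspanin Cd9 (0.80, adjusted p = 0.0279; named after its value was seen) rose with it, while the Schwann cell precursor cadherin Cdh19 fell (-1.21, adjusted p = 0.0109). The list was higher (camera, adjusted p = 0.00955; adjusted p = 0.236 with an estimated correlation). In the Notch pathway, 3 of 14 genes rose and 0 fell (4 and 0 adjusted over the list alone): the receptor Notch1 (1.99, adjusted p = 0.000959), the glycosyltransferase Mfng, which modifies it (2.91, adjusted p = 0.00348), and the target Hes1 (1.08, adjusted p = 0.0491). The list was higher (adjusted p = 0.00955; adjusted p = 0.168 with an estimated correlation). Of 29 genes of receptor tyrosine kinases and ERK feedback, 5 rose and 0 fell (12 and 4 adjusted over the list alone), among them the cyclin Ccnd1 (1.86, adjusted p = 0.00189), the growth factor Pdgfb (2.68, adjusted p = 0.0101), the kinase Axl (1.68, adjusted p = 0.00588) and the AP-1 factor Fosl2 (1.21, adjusted p = 0.0242). This list was also higher (adjusted p = 0.00955; adjusted p = 0.236 with an estimated correlation).

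Fibroblast markers, fixed as markers of another cell type, were higher too: 3 of 8 rose and 0 fell (5 and 0 adjusted over the list alone), namely Col1a1 (2.68, adjusted p = 0.0102), Col5a1 (1.31, adjusted p = 0.0253) and the receptor Pdgfrb (1.84, adjusted p = 0.00237), with camera at an adjusted p of 0.00955 (adjusted p = 0.163 with an estimated correlation). Of 26 genes of hypoxia and glycolysis, 1 rose, Ndrg1 (1.59, SE 0.30), and 0 fell (the same counts adjusted over the list alone); the list was higher (adjusted p = 0.00955; adjusted p = 0.754 with an estimated correlation). Genes reported elsewhere to respond to FOXD3 moved both ways, with 3 of 12 up and 3 down (4 and 4 adjusted over the list alone) and the list did not pass (camera, adjusted p = 0.722; median -0.19, mean 0.06). In this list the cell cycle inhibitors Cdkn1a (0.65, adjusted p = 0.197) and Cdkn1b (-0.60, adjusted p = 0.101) and the GTPase Rnd3 (-0.76, adjusted p = 0.369) passed with the replicate number as a block and not without it (adjusted p = 0.0225, 0.0189 and 0.0172). The neuronal list was not called (7 tested, adjusted p = 0.123; 0.0453 without the 3 arrays numbered 1, and 0.0453 to 0.280 over 19 alternatives), although the intermediate filament gene Prph rose (2.03, adjusted p = 0.0291). Pluripotency genes were not called either (6 tested, adjusted p = 0.914). Antigen presentation (0.0801), heat shock (0.0824), and lysosome and autophagy (0.0782) missed an adjusted p of 0.05 and passed, each higher, with the block (0.0467, 0.0323 and 0.0226). The 12 remaining lists given here are those of G2/M and S phase, p53 targets, interferon response, ER stress, adhesion, the Wnt and the BMP and TGF-beta pathways, cholesterol synthesis, ribosomal proteins, Groucho corepressors and leukocyte markers. They had adjusted p-values from 0.123 to 0.914. Keratinocyte and endothelial markers had 1 and 4 members bright enough and were not tested.

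In all, 438 of 10916 genes changed with FoxD3, 316 up (72.1%) and 122 down, and 255 of them by a log2 change of at least 1. With the replicate number as a block there were 2297 (1292 up, 1005 down), among them all 438. The groups were fully apart for 1254 genes (11.5%, where chance gives 2.86% with the pairing left aside). Of 53 named genes called here, 38 passed with each array left out in turn. Ahr, Fign, Thsd7a, Fabp3, Snai2, Col1a1, Col5a1, Bcl2, Tfap2a, Rab32, Prph, Hes1, Fosl2, Mmd and Slc40a1 did not, their highest adjusted p lying between 0.0652 and 0.589, that of Tfap2a through its other probe set. Of the 8 lists, Notch and fibroblast markers passed with each array left out in turn, and the other 6 each lost the call without at least 1 array: pigment without empty-vector 1 (adjusted p = 0.0670), receptor tyrosine kinases without empty-vector 2 (0.168), glia without FoxD3 2 (0.106) or empty-vector 3, hypoxia without empty-vector 1 (0.160) or 2 others, melanocyte regulators without any of 5 (highest 0.106, without FoxD3 2) and neural crest without any of 9 (highest 0.174, without empty-vector 3). Beside Erbb3, the mean of all probe sets ended the calls of Fign, Prickle1, Thsd7a, Arid5b, Snai2, Bcl2, Fosl2 and Mmd (adjusted p = 0.0629 to 0.425), a pseudocount of 1 those of Fabp3, Prph, Hes1 and Pdgfb (0.0528 to 0.0964). No filter ended those of Snai2, Rab32, Hes1, Mmd and Slc40a1 (0.0543 to 0.103). A pseudocount of 64 ended those of Col1a1 and Slc40a1, the values as deposited those of Tfap2a, Rab38, Mmd and Slc40a1, and leaving out probe sets ending in _x_at that of Snai2. Leaving out the arrays numbered 1 ended those of Fign, Thsd7a, Rab32 and Slc40a1. One of 4 arrays lay apart for Ahr, Tyr and Snai2 with FoxD3, and for Otud1, Prickle1, Gadd45b and Ccnd1 with the empty vector.

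**Figure D2:**
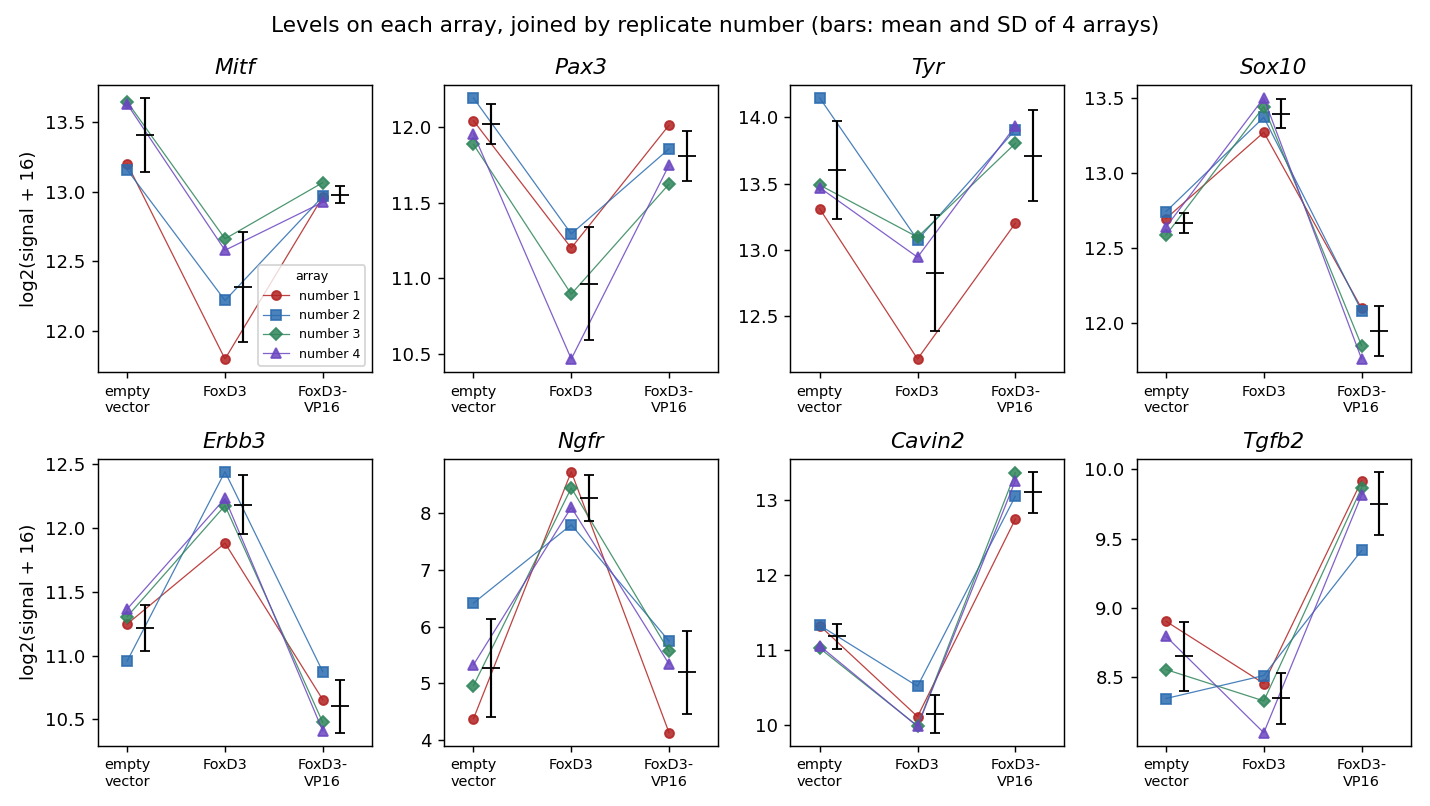
Normalized log2(intensity + 16) of 8 genes on each of the 12 arrays, with lines joining arrays of the same replicate number and bars giving the group mean and SD (n = 4). Mitf went from 13.4 with the empty vector to 12.3 with FoxD3, and Ngfr from 5.27 to 8.27; Sox10 was at 12.7, 13.4 and 11.9 with the empty vector, FoxD3 and FoxD3-VP16.

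FoxD3-VP16 against empty vector. With the activation domain, Sox10 fell and Cavin2, Postn and Ccn2 rose. Mitf was called with the replicate number as a block and not without it, and Pax3 in neither fit. Sox10 was 1.64-fold lower (log2 change -0.72, SE 0.11, adjusted p = 0.0178), at 11.9 ± 0.17 against 12.7 ± 0.07 (SD, n = 4). It did not pass with the mean of all its probe sets (-0.64, adjusted p = 0.193; 6.28e-06 to 0.193 over 24 alternatives). The caveolar protein Cavin2 rose 3.80-fold (1.93, SE 0.17, adjusted p = 0.000452), periostin, Postn, a matrix protein, 4.62-fold (2.21, SE 0.27, adjusted p = 0.00312), and the matricellular growth factor Ccn2 5.82-fold (2.54, SE 0.42, adjusted p = 0.0192).

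Scube3 had the largest rise (3.40, SE 0.58, adjusted p = 0.0232), followed by Vasn, a TGF-beta binding protein (2.74), Ccn2, the Rac and Cdc42 activator Dock10 (2.43), the chemokine receptor Ackr3 (2.37), the phosphatase Dusp14 (2.23), Postn, the Cdk-binding Cables1 (2.10), the lipid antigen presenter Cd1d1 (1.95) and Cavin2. Scube3 and Cables1 lay below 5.98 with the empty vector. Without the block 8 genes fell, all of them named by the rule: Gm829 (-1.38), the integrin subunit Itga4 (-1.18), the synaptotagmin Syt4 (-1.17), Gpr137b (-1.11), Syt9 (-0.90), Naf1 (-0.84), Enho (-0.74) and Sox10. With the block 591 genes fell and 626 rose, so the small number of falls depends on the fit. Another probe set of Itga4 had a change of 0.10.

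Melanocyte lineage regulators were lower as a list (19 tested, 0 up, 1 down, and 0 and 2 adjusted over the list alone; camera, adjusted p = 0.0479; adjusted p = 0.214 with an estimated correlation), and so were neural crest specifiers (16 tested, 0 up, 1 down over all genes and over the list alone; adjusted p = 0.0222; adjusted p = 0.136 with an estimated correlation). Without the block, Sox10 is the called member of both. Mitf had a log2 change of -0.43 (SE 0.18, adjusted p = 0.436), Erbb3 of -0.62 (adjusted p = 0.135) and Tyrp1 of -0.25 (adjusted p = 0.296), and the 3 were lower with the replicate number as a block (adjusted p = 0.0282, 0.0131 and 0.0092). Rnd3 (-0.85), Cdkn1a (-0.64) and Mlana (0.17) also passed with the block and not without it (adjusted p = 0.0188, 0.0399 and 0.0444). So did Rab38 (-0.40) and Atp7a (0.60) of the pigment list and the melanocyte regulator Bcl2 (-0.46), with adjusted p-values of 0.00121, 0.00168 and 0.0223. Pax3 (-0.21) and Tyr (0.11) passed in neither fit. The same held for Dct (-0.12), Pmel (-0.17), Snai2 (-0.22), Cdkn1b (0.07), Sox9 (0.01) and Ednrb (0.08), with adjusted p-values from 0.813 to 0.998 without the block and 0.0659 to 0.989 with it. Kit and Twist1, not tested, had changes of -0.13 and -0.30, and a still dimmer probe set of Kit one of 0.82. Tyr passed with array quality weights (0.36, adjusted p = 0.0179; changes of -0.05 to 0.36 and adjusted p of 0.0179 to 1 over 24 alternatives). The pigment list had an adjusted p of 0.604 (24 tested, 0 up, 0 down by limma at an adjusted p of 0.05; 3 at an unadjusted p under 0.05; 0 and 1 adjusted over the list alone; fry, adjusted p = 0.789).

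In the BMP and TGF-beta pathway, 3 of 16 genes rose and 0 fell (3 and 1 adjusted over the list alone): Ccn2, the ligand Tgfb3 (1.46, adjusted p = 0.0354) and the ligand Tgfb2 (1.10, adjusted p = 0.0192). The list was higher (camera, adjusted p = 0.0271; adjusted p = 0.627 with an estimated correlation). Fibroblast markers were higher, with 2 of 8 up and 0 down over all genes and over the list alone, Postn and Pdgfrb (1.60, adjusted p = 0.0240; camera, adjusted p = 0.00369; adjusted p = 0.0910 with an estimated correlation). In the Wnt pathway, 1 of 14 genes rose, the receptor Fzd7 (0.92, adjusted p = 0.0371), and 0 fell (2 and 0 adjusted over the list alone). The list passed (adjusted p = 0.0388; adjusted p = 0.627 with an estimated correlation) but not with the block (adjusted p = 0.0571). Another probe set of Fzd7 had a change of -0.03. Cholesterol synthesis genes were higher and ER stress genes lower as lists, although limma called 0 of 21 and 0 of 28 members over all genes (3 and 2 had an unadjusted p under 0.05) and 0 and 1, the latter lower, adjusted over the list alone. Their camera adjusted p-values were 0.0131 and 0.0406 (adjusted p = 0.812 for both with an estimated correlation), and fry gave 0.669 for both. Genes reported to respond to FOXD3 had 1 of 12 up, Tgfb2, and 1 down, Sox10 (1 and 2 adjusted over the list alone; adjusted p = 0.191). The 18 other lists given here that did not pass had adjusted p-values from 0.211 to 0.803, among them glia (13 tested, 0.723; median -0.07, mean 0.04), neuron (7 tested, 0.687) and pluripotency (6 tested, 0.803).

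In all, 65 genes changed, 57 up and 8 down; with the replicate number as a block there were 1217 (626 up, 591 down), among them all 65. The groups were fully apart for 623 genes (5.71%, where chance gives 2.86% with the pairing left aside). The count was 13 without the FoxD3-VP16 array numbered 4, 14 without the empty-vector array numbered 3 and 277 without the 3 arrays numbered 1, where the lists of melanocyte regulators, neural crest, ER stress, Wnt, and BMP and TGF-beta did not pass (adjusted p = 0.0513 to 0.395; 0.000435 to 0.812 over their alternatives). Of 28 named genes called here, Syt4, Postn, Vasn, Cavin2, Adh1 and Arid5b passed with each array left out in turn. The other 22, Sox10, Ccn2 and Scube3 among them, did not, with highest adjusted p-values from 0.0968 to 0.186. Of the 7 lists, fibroblast markers passed with each array left out in turn. Neural crest did not without empty-vector 3 (adjusted p = 0.0721), BMP and TGF-beta without empty-vector 2 (0.267) or FoxD3-VP16 3, cholesterol synthesis without empty-vector 3 (0.321) or 4, Wnt without any of 5 (highest 0.737, without FoxD3-VP16 1), ER stress without any of 6 (highest 0.621, without empty-vector 2) and melanocyte regulators without any of 9 (highest 0.162, without FoxD3-VP16 2). Melanocyte regulators also did not pass with the values as deposited (adjusted p = 0.0737; 0.0385 to 0.214 over 19 alternatives). Beside Sox10, the mean of all probe sets ended the calls of Enho, Gpr137b, Itga4, Cables1, Cd1d1, Dock10, Fzd7, Mmd and Arid5b (adjusted p = 0.0562 to 0.762). No filter ended those of Enho, Gm829, Naf1, Syt9, Cd1d1, Tgfb3 and Cited2 (0.0531 to 0.0749). The values as deposited ended those of Cd1d1, Mmd and Cited2, and a pseudocount of 1 those of Cd1d1 and Cited2. The array numbered 1 lay apart for Ackr3 and Syt9 with the empty vector and for Postn with FoxD3-VP16.

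FoxD3-VP16 against FoxD3. The direct test of the exchanged domain does not use the empty-vector arrays for its means and gave the most changed genes. Sox10 was 2.72-fold lower with FoxD3-VP16 than with FoxD3 (log2 change -1.45, SE 0.11, adjusted p = 1.52e-05), Erbb3 2.99-fold lower (-1.58, SE 0.16, adjusted p = 8.56e-05) and Ngfr was lower, at 5.20 ± 0.73 against 8.27 ± 0.41 (SD, n = 4; log2 change -3.07, SE 0.47, adjusted p = 0.00123; -4.15 to -2.04 over 22 alternatives, the pseudocount among them). Pax3 (0.84, SE 0.17, adjusted p = 0.00845), Mitf (0.66, SE 0.18, adjusted p = 0.0389) and Tyr (0.89, SE 0.24, adjusted p = 0.0360) were higher. All 6 went the same way in 4 of 4 pairs.

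The largest falls from FoxD3 to FoxD3-VP16 were in Col2a1 (-4.37), Gadd45b (-3.84), Fabp3 (-3.79), Fbxl16 (-3.65), the neuromuscular adaptor Dok7 (-3.31), Padi3 (-3.29), the cadherin Celsr3 (-3.14), Ngfr, Zfp469 (-3.01) and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum (-2.98). The largest rises were in Cavin2 (2.96), Dock10 (2.86), Thsd7a (2.77), the kinase Sgk1 (2.77), the ferroxidase ceruloplasmin, Cp (2.70), Cd1d1 (2.66), Arid5b (2.65), the iron exporter Slc40a1 (2.64), the alcohol dehydrogenase Adh1 (2.56) and Ackr3 (2.53). The dimmer group lay below the brightness limit of 5.98 for Col2a1, Padi3, Celsr3, Ngfr, Mfng, Pdgfb and Prph with FoxD3-VP16 and for Ackr3 and Cd1d1 with FoxD3, so the size of these changes depends on the pseudocount.

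In the Notch pathway, 4 of 14 genes were lower and 0 higher, over all genes and over the list alone: Mfng (-2.71), Notch1 (-2.12), Hes1 (-1.48) and Rfng (-0.78), with adjusted p-values from 0.000261 to 0.0160. The list was lower (camera, adjusted p = 0.0388; adjusted p = 0.622 with an estimated correlation) but did not pass with the block (adjusted p = 0.0658), and another probe set of Rfng had a change of 0.18. Of 29 genes of receptor tyrosine kinases and ERK feedback, 10 were lower and 1 higher (13 and 3 adjusted over the list alone), with Pdgfb (-2.74), Ccnd1 (-2.68), Erbb3 and Fosl2 (-1.55) the lower ones of largest size; the list was lower (adjusted p = 0.0269; adjusted p = 0.622 with an estimated correlation). Cholesterol synthesis was higher, with 2 of 21 genes up and 0 down over all genes and over the list alone, the isomerase Idi1 (0.64, adjusted p = 0.0367) and the sterol carrier Stard4 (0.81, adjusted p = 0.0183; camera, adjusted p = 0.0388; adjusted p = 0.653 with an estimated correlation).

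Of 19 melanocyte regulators, 3 were higher (Pax3, Tfap2a at 0.76, Mitf) and 1 lower (Sox10), with 6 and 3 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.246). Of 24 pigment genes, 2 were higher, Tyr and the copper transporter Atp7a (1.19, adjusted p = 0.00238), and 0 lower, over all genes and over the list alone (adjusted p = 0.0898). Mlana was higher with the block (0.30, adjusted p = 0.193 without it and 0.000496 with it), as was Snai2 (0.54, 0.104 and 0.0108). Tyrp1 (0.03), Dct (-0.05), Pmel (-0.05), Rnd3 (-0.09), Ednrb (0.51) and Sox9 (0.66) passed in neither fit, with adjusted p-values from 0.368 to 0.939 without the block and 0.115 to 0.772 with it. Sox9 passed with array quality weights (1.06, adjusted p = 0.00119; 0.00119 to 0.860 over 23 alternatives) and without the 3 arrays numbered 1 with the block (0.95, adjusted p = 0.0155). Kit, which was not tested, had a change of -0.94, lower in 4 of 4 pairs, and Twist1 one of 0.04. A still dimmer probe set of Kit had a change of 0.30. Of 16 neural crest specifiers 3 were higher, including Alx1 (1.05), and 3 lower, including the GTPase Rhob (-1.17), with 5 and 3 adjusted over the list alone and the list not passing (adjusted p = 0.607; median 0.22, mean -0.11). Glial genes had 1 higher, Cdh19 (1.07), and 3 lower, led by Ngfr and Cnp (-2.80), of 13 (2 and 4 adjusted over the list alone; adjusted p = 0.0898). Of 12 genes reported to respond to FOXD3, 4 were higher, including Tgfb2 (1.41), and 4 lower (6 and 4 adjusted over the list alone; adjusted p = 0.876; median 0.37, mean -0.19). Cdkn1a was lower (-1.29, adjusted p = 0.00542) and Cdkn1b higher (0.67, adjusted p = 0.0399). Prph was lower (-1.87), with the neuronal list at an adjusted p of 0.357 and the pluripotency list at 0.910. Antigen presentation (0.0664), ER stress (0.0599) and hypoxia (0.0898) missed an adjusted p of 0.05 and passed, each lower, with the block (0.0497, 0.00582 and 0.0497). The remaining lists given here had adjusted p-values from 0.105 to 0.980.

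In all, 1045 genes differed between both constructs, 485 higher and 560 lower with FoxD3-VP16; with the replicate number as a block there were 3498 (1592 and 1906), among them all 1045. The groups were fully apart for 1984 genes (18.2%, where chance gives 2.86% with the pairing left aside). Of 45 named genes called here, 37 passed with each array left out in turn; Cdkn1b, Idi1, Stard4, Tfap2a, Mitf, Tyr, Prph and Rfng did not, with highest adjusted p-values from 0.0520 to 0.724. Each of the 3 lists lost its call without some array: receptor tyrosine kinases without FoxD3-VP16 2 (adjusted p = 0.0582), Notch without FoxD3 1 (0.0801) or FoxD3-VP16 2, and cholesterol synthesis without any of 6 (highest 0.0833, without FoxD3 1). Notch also did not pass without the 3 arrays numbered 1 (adjusted p = 0.0646; 0.00924 to 0.622 over 19 alternatives). The mean of all probe sets ended the calls of Mitf (adjusted p = 0.102; 0.000319 to 0.105 over 24 alternatives), Cdkn1b, Idi1, Tfap2a and Rfng (0.0544 to 0.428). No filter ended those of Mitf (0.0572), Cdkn1b and Idi1. Leaving out the arrays numbered 1 ended those of Cdkn1b and Idi1, the values as deposited that of Tfap2a, and a pseudocount of 1 that of Prph. One array lay apart for Tyr, Atp7a and Rfng with FoxD3 and for Sgk1 and Ccnd1 with FoxD3-VP16.

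Genes shared by both constructs. Against the empty vector, 17 genes were called with both constructs. FoxD3 lowered and FoxD3-VP16 raised 9, including Cavin2 (-1.04 and 1.93), Arid5b (-1.40 and 1.24), Slc40a1 (-1.02 and 1.62), Adh1 (-0.99 and 1.56) and the transcriptional coregulator Cited2 (-1.33 and 0.85). Sox10 was the 1 gene raised by FoxD3 and lowered by FoxD3-VP16. Both raised 5 genes, Scube3 (4.00 and 3.40), Vasn (1.90 and 2.74), Pdgfrb (1.84 and 1.60), Gm19439 (1.80 and 1.56) and the membrane protein Mmd (0.74 and 1.04), and both lowered Syt4 (-1.19 and -1.17) and Syt9 (-1.10 and -0.90), calcium sensors of vesicle release. For these 7 the direct comparison of the constructs was not called (adjusted p = 0.171 to 0.959), although Vasn passed there with the block (adjusted p = 0.0179).

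That makes 10 genes in opposite and 7 in the same direction. Independent lists of these sizes would share 0.637 genes lowered by FoxD3 and raised by FoxD3-VP16, 0.232 of the reverse kind, 1.65 raised by both and 0.0894 lowered by both. Unchanged groups simulated against the same empty-vector arrays shared 0 genes in either direction in 100 draws, with limma and with the block, but such groups had a mean of at most 0.04 called genes, so this says nothing of lists with real effects that share controls. With the block, 175 genes were opposite and 199 the same, so more went the same way. More did so too without the 3 arrays numbered 1 (30 and 31) and with array quality weights (433 and 1220). With the block, 117 genes were lowered by FoxD3 and raised by FoxD3-VP16 against 57.6 for independent lists, 105 lowered by both against 54.4, 94 raised by both against 74.1, and 58 raised by FoxD3 and lowered by FoxD3-VP16 against 69.9. With the empty-vector arrays divided 2 and 2 between the constructs, 1 to 25 genes were opposite and 0 to 9 the same over 6 divisions, with more opposite in 4 and equal counts in 2. With the block as well, 22 to 356 were opposite and 14 to 129 the same, with more opposite in all 6 divisions, whereas shared controls gave 175 and 199. All 4 arrays of a construct were set against controls of 2 numbers, so differences between numbers enter both changes with opposite signs. With the block, both changes share a part of the difference between the constructs, again with opposite signs. These divisions thus lean towards opposite directions by construction and decide nothing. Across genes, which are not independent replicates, both changes correlated at a Pearson correlation of 0.135 and a Spearman correlation of 0.146. Unchanged groups sharing the controls gave a mean r of 0.499. The covariance was 0.0228 against a simulated 0.0226, a difference of 0.000202, and with separate controls r lay between -0.07 and 0.03.

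**Figure D3:**
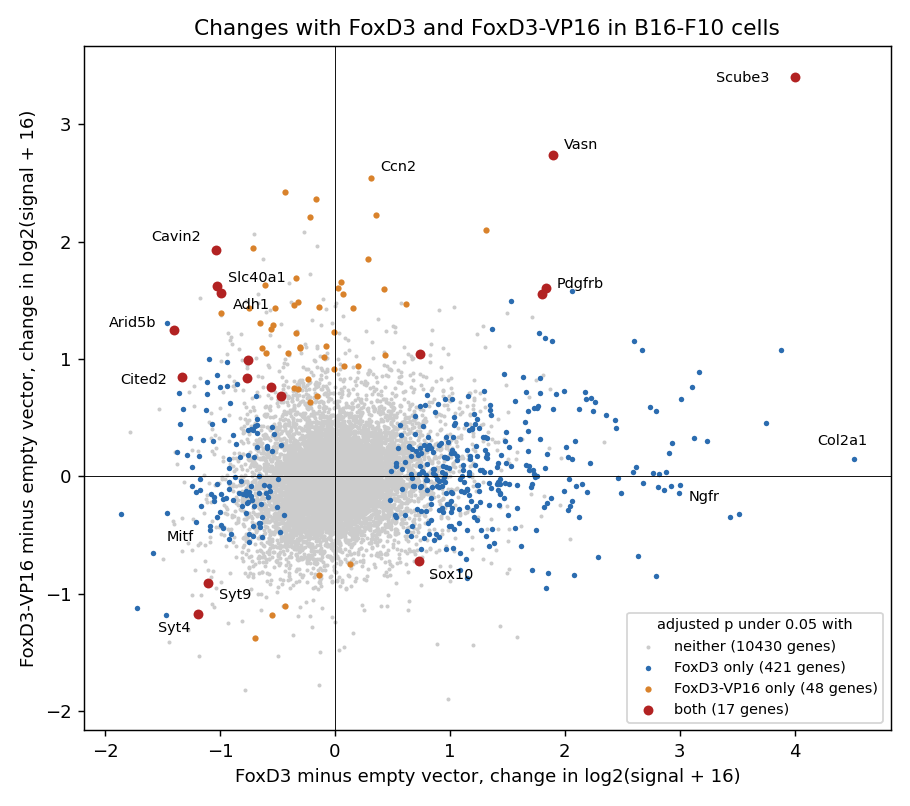
Log2 change with FoxD3 (horizontal axis) against that with FoxD3-VP16 (vertical axis), both relative to the empty vector, for the 10916 tested genes; colours mark genes with an adjusted p under 0.05 for one or both constructs. Genes called for both lie in all 4 quadrants, with Scube3 at 4.00 and 3.40, Cavin2 at -1.04 and 1.93 and Sox10 at 0.73 and -0.72.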

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

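The tests of hybridization controls and of RNA 5' ends on the arrays numbered 1 were chosen only after those arrays had been seen to stand apart, and the splits with the block were narrowed to those that part all 4 pairs after their counts over all 35 had been seen. How the groupings of the 12 arrays were read was also settled after their values were known; the tests of the other splits and of bright genes were set beforehand.

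In 5 of 15 groups of array measures 1 of 4 arrays lay far from the others, each time the array numbered 1. Its gap to the next array was 0.852 of the group's range for the array median with FoxD3 and 0.882 with FoxD3-VP16, 0.850 for the Gapdh 3' minus 5' difference with FoxD3, and 0.917 with the empty vector and 0.883 with FoxD3-VP16 for the 18S probe sets. Among groups of named genes, 20 of 270 had such an array, where chance gives about 1 in 20 (13.5); it was number 1 in 11, number 2 in 8 and number 3 in 1. Number 1 was apart for Dct (0.869), Ednrb (0.887), Sox9 (0.895) and Postn (0.866) with FoxD3-VP16, for Snai2 (0.880), Tyr (0.835), Postn (0.845), Atp7a (0.849) and Rfng (0.889) with FoxD3, and for Syt9 (0.863) and Ackr3 (0.868) with the empty vector. Number 2 was apart for Ahr (0.892) and Gm19439 (0.840) with FoxD3, for Otud1 (0.881), Prickle1 (0.930), Gadd45b (0.894) and Ccnd1 (0.835) with the empty vector, and for Ccnd1 (0.885) and Sgk1 (0.838) with FoxD3-VP16. Number 3 was apart for Rab32 with FoxD3-VP16 (0.927).

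Probe sets with no single gene symbol entered no comparison, and 3646 of 10092 were bright enough to test. Of these, 17 were called for FoxD3 against empty vector, 12 for FoxD3-VP16 against empty vector and 148 between the constructs (176, 101 and 498 with the replicate number as a block).

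The arrays numbered 1 stand apart in every group. Noise of dim probe sets alone is argued against: in the 2729 brightest genes their deviations had 1.88 to 2.36 times the SD of those on numbers 3 and 4. Numbers 3 and 4 are alike and pull the group mean towards themselves. A part of this ratio is therefore built in, and its size was not tested. Less labelled RNA relative to the hybridization controls, which were 2.63 to 2.94 log2 units brighter than on numbers 3 and 4, and RNA with less of its 5' end, with a Gapdh gap to the next array of 0.616 to 0.790 and the highest actin difference in 3 of 3 groups, both remain open and may both apply. No biological explanation was tested, since the labels do not say what the numbers share.

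For FoxD3 against empty vector, 1 of the 35 splits of the 8 arrays gave as many genes, the real one (438). The highest other gave 161, a split of numbers 1 and 2 against 3 and 4. At an unadjusted p under 0.05 that other split gave 2184 genes, more than the real 1762. The share of 1 in 35 is under the bound of 5%, but the 35 splits leave the pairing by number aside, so chance is not excluded for paired arrays. For FoxD3-VP16 against empty vector 2 of 35 gave as many (65, highest other 211), so chance is not excluded by this count. That other split sets both arrays numbered 1 against both numbered 2. It keeps the arrays numbered 3 and 4 parted by vector as in the real grouping. It thus mixes a structure by number with part of the real comparison, and called 509 genes with the block. It is therefore no clean case of chance. Between the constructs, 1 of 35 gave as many, the real one (1045, highest other 0), which is under 5% but again leaves the pairing aside. With the block, 1 of the 8 splits that part all 4 pairs, the real one, gave as many genes in each comparison (2297, 1217 and 3498; highest other 0 in each), and 8 splits are too few for a share under 5%. Over all 35 splits the highest other with the block was 1, 509 and 0. The 7 other splits that part all 4 pairs called 0 genes by limma in each comparison, with and without the block; at an unadjusted p under 0.05 they gave up to 499, 424 and 442 genes, against 1762, 1129 and 2516 for the real ones. Over all 35 splits, 2, 4 and 1 gave as many genes at that p as the real one, itself included, with highest others of 2184, 2598 and 2244. For gene lists chance was not excluded: 5 of 35 splits gave as many for FoxD3 (8; highest other 11), 13 for FoxD3-VP16 (7; highest other 11) and 25 between the constructs (3; highest other 10); the 7 that part all 4 pairs gave up to 6, 9 and 4. For the genes called with both constructs, 1 of 100 groupings of the 12 arrays (99 drawn and the real one) gave as many in opposite directions (10; highest other 0) and 1 in the same direction (7; highest other 0). This decides nothing, because 0 of the 99 drawn groupings called a gene for both constructs' comparisons, so none could share any; the draws also left the pairing aside.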

How the results depend on the processing

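The fits without the arrays numbered 1 and the block of 3 levels were chosen after seeing the data. No named gene or list turned its direction where it was called, with or without an alternative; 13 of 165 results of named genes had either sign over the alternatives, uncalled where the sign differed. Counts below are for FoxD3, FoxD3-VP16 and between the constructs, then opposite and same directions. The replicate block gave 2297, 1217, 3498, 175 and 199, and 5 lists between the constructs; it changed no other call of a list, or of a gene in a comparison for which the rule names it, than those given beside the results. In comparisons for which the rule does not name them, 10, 13 and 9 genes named elsewhere were also called with the block and not without it. Without the arrays numbered 1 there were 870, 277, 1815, 30 and 31, and 2 lists for FoxD3-VP16; with the block too, 1991, 1439, 3355, 164 and 236. The block of 3 levels gave 2575, 1510, 3819, 220 and 255. Array quality weights gave 4193, 3465, 4455, 433 and 1220, with 1660 up and 1805 down for FoxD3-VP16 in place of 57 and 8. The excess of opposite over same directions (10 and 7) was turned by each of these 5 and without empty-vector 2 (6 and 12), and with a log2 change of at least 1 (3 and 5); there was none without the filter (5 and 5), with the mean of all probe sets (6 and 6) and without FoxD3 3 or 4 (5 and 5). The cause was not tested for any of these. A log2 change of at least 1, which keeps fewer genes by construction, left 255, 508 between the constructs and 3 opposite. The lowest 60% left out, which tests fewer genes, left 274 for FoxD3. No filter gave 5 opposite genes, r = 0.269, and 3 lists for FoxD3-VP16 and 6 between the constructs; the mean of all probe sets gave 6 opposite, and the 8 arrays alone, with fewer samples, 20 for FoxD3-VP16. An estimated inter-gene correlation left 0, 0 and 0 lists (camera; fry called 9, 3 and 3, and 4, 3 and 1 had an unadjusted p under 0.05). The values as deposited and pseudocounts of 1 and 64 moved no count by over 1.5 times. Of the 126 calls of named genes, 8 ended with the values as deposited, 7 with a pseudocount of 1, 2 with 64, 15 without the filter, 24 with the mean of all probe sets, 1 without probe sets ending in _x_at, and 6 without the arrays numbered 1 (1 with the block too). Of the 18 calls of lists, 2 ended with the values as deposited, 2 with a pseudocount of 64, 6 without the filter, 3 with the block, and 6 without the arrays numbered 1 (5 with the block too).

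With each array left out in turn the counts were 197 to 555, 13 to 82, 602 to 1214, 3 to 10 opposite and 2 to 12 the same, r was 0.0979 to 0.302 (0.254 and 0.302 without empty-vector 1 and 2), and lists numbered 4 to 10, 3 to 8 and 2 to 6. For FoxD3 the count was 241 and 261 without the empty-vector arrays 3 and 4, and 215 and 197 without FoxD3 arrays 3 and 4. For FoxD3-VP16 it was 14 and 16 without empty-vector 3 and 4, 36 and 42 without FoxD3 3 and 4, and 15 and 13 without FoxD3-VP16 3 and 4. Between the constructs it was 652 and 602 without FoxD3 3 and 4, and 645 and 663 without FoxD3-VP16 3 and 4. Opposite genes were 3 without empty-vector or FoxD3-VP16 3 or 4, 5 without FoxD3 3 or 4 and 6 without empty-vector 2; the same direction held 2 without empty-vector or FoxD3-VP16 3 or 4 and 12 without empty-vector 2. Of the 18 calls of lists, 3 held with every array left out in turn. Lists fell to 4 for FoxD3 without empty-vector 3, and for FoxD3-VP16 to 3 without it and 4 without empty-vector 4, FoxD3 1 or FoxD3-VP16 3; between the constructs they were 6 and 5 without empty-vector 2 and 3. Fewer samples are part of this by construction, but leaving out an array numbered 1 or 2 removes as many. For FoxD3-VP16 the count was then 45 to 82, against 13 to 42 without an array numbered 3 or 4. In the other comparisons these ranges overlapped. The arrays numbered 3 and 4 deviated alike, so the fit without the block may treat them as more independent than they are. This was not tested. Dim genes lie near the floor of the log2 scale at 4, which limits what their signal can show.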

Other observations

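The gene families below, the way raised genes were read, the family tests without the genes named above, the comparison with raised genes and the covariances of single numbers were chosen only after the data had been seen. The other tests were set beforehand. Because the families were chosen with these data in view, the p-values of Fisher's exact test given for them are descriptive. They are no independent support, also without the named genes.

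Of 18 collagen genes tested, 8 were higher with FoxD3 and 0 lower than with the empty vector: Col2a1 (log2 change 4.52), Col11a2 (2.80), Col1a1 (2.68), Col7a1 (2.49), Col9a3 (1.72), Col27a1 (1.68), Col16a1 (1.43) and Col5a1 (1.31). That is more than among all tested genes (Fisher's exact test, adjusted p = 5.23e-06 over 27 tests of 9 families; 5 of 15 and adjusted p = 0.00222 without the genes named above). With the replicate number as a block 9 were higher and 2 lower, Col4a5 (-0.61, adjusted p = 0.0349) and Col9a1 (-0.77, adjusted p = 0.0265). With FoxD3-VP16 limma called 0 of 18 (2 with the block, and 4 at an unadjusted p under 0.05), and between the constructs 7 were lower and 2 higher, Col9a1 (2.27) and Col4a5 (1.13; adjusted p = 0.000193; 0.00222 without the genes named above; with the block 8 were lower and 4 higher). Ephrins and Eph receptors had 3 of 11 higher with FoxD3, Epha2 (2.82), Efna3 (2.29) and Efna1 (1.83; adjusted p = 0.0281; with the block 4 were higher and 1 lower, Epha3 at -1.17), and between the constructs Epha2 (-2.80) and Efna3 (-2.97) were lower and Epha3 (2.01) higher (adjusted p = 0.181; 4 lower and 2 higher with the block). With FoxD3-VP16 limma called 0 of the 11 (2 at an unadjusted p under 0.05), and with the block 2 were higher, Efna1 (1.18) and Epha3 (0.84).

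Sox factors moved apart from one another. With FoxD3, Sox10 rose (0.73) while Sox11 (-1.03) and Sox6 (-0.99) fell (3 of 8, adjusted p = 0.0139), as did Sox4 with the block (-0.76, adjusted p = 6.15e-05); from FoxD3 to FoxD3-VP16, Sox11 (1.89), Sox4 (1.59) and Sox6 (0.84) were higher and Sox10 lower (-1.45; adjusted p = 0.0164), and Sox5 was higher with the block (0.70). Without the genes named above the Sox tests did not pass (adjusted p = 0.0647 and 0.0542). With FoxD3-VP16 against the empty vector, Sox11 (0.86) and Sox4 (0.83) were higher with the block (adjusted p = 0.000781 and 0.000133) and not without it (0.0804 and 0.240). Between the constructs, Kruppel-like factors (6 of 14, adjusted p = 0.00783; 0.00482 without the genes named above; 9 with the block) and dual specificity phosphatases (6 of 16, adjusted p = 0.0139; 0.0453 without them; 8 with the block) changed in both directions, with Klf12 (1.77) and Dusp14 (1.87) higher and Klf10 (-2.31) and Dusp8 (-1.71) lower. Semaphorins and plexins, integrins and potassium channels had adjusted p-values from 0.181 to 1; with the block, 8 semaphorins and plexins of 22 were higher and 2 lower with FoxD3, and 2 higher and 9 lower between the constructs, where 4 of 13 integrins were higher and 2 lower. Against the empty vector the block called 5 Kruppel-like factors and 5 dual specificity phosphatases with FoxD3, and 5 and 3 with FoxD3-VP16, in both directions. Synaptotagmins were looked at because Syt4 and Syt9 had been named, so their test decides nothing and is not given. Values as deposited gave the named members the same directions.

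More genes changed with FoxD3 than with FoxD3-VP16, by a ratio that depends on the fit: 6.74, but 1.89 with the replicate number as a block, 1.21 with array weights, 16.6 with only the 8 arrays of each comparison, and 3.77 to 25.5 with single arrays left out (3.77 without FoxD3 1, 25.5 without FoxD3-VP16 4). The quantile normalization added here is argued against, since the ratio was 7.21 with the values as deposited. Those values already share one scale factor rule, so the scaling done before deposit was not tested. Smaller changes of RNA levels with FoxD3-VP16 are a candidate explanation: between separate sets of 2 numbers, the covariance of the changes was 2.07 to 3.01 times larger for FoxD3 in the 3 ways to divide them. A part of the spread of the arrays numbered 1 cannot be told apart from this, because without them the ratio went from 6.74 to 3.14, and with the block from 1.89 to 1.38, on either side of the bound of 1.5, which named no fit and was read with both values known; for single numbers without number 1 the covariance was larger with FoxD3 in 3 of 3 pairs, least between numbers 3 and 4 (0.223 against 0.185).

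The changes with both constructs had r = 0.135 over genes. Shared control arrays alone gave as much covariance, 0.0206 to 0.0249 in simulated unchanged groups against 0.0228 observed. With separate controls the covariance lay between -0.0171 and 0.00538. The changes are thus not shown to go together beyond what shared controls give. A hypothesis that FoxD3-VP16 raises the genes that FoxD3 lowers was tested on the 200 genes most lowered by FoxD3 in 2 of the numbers: their mean change with FoxD3-VP16 in the other 2 was 0.0312 to 0.213, above 0 in all 6 divisions, but only 48% to 64% of them were higher. The genes most raised by FoxD3 also had means above 0, up to 0.109, so whether lowered genes are special cannot be told apart here. Whether FoxD3-VP16 lowers the genes FoxD3 raises stays open too: a mean at or above 0 had been set as the bound against it, but 46% to 52.5% of them were lower, and a mean over genes that went both ways decides nothing.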
